A study of Homo sapiens with 17 samples.

How the data were processed

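The series holds 17 samples of PC3 cells, a human prostate cancer cell line, by the labels: 8 RNA sequencing libraries and 9 chromatin immunoprecipitation sequencing (ChIP-seq) samples. The RNA libraries form 4 groups of 2. They are cells transfected with a control siRNA (siCTL) or with an siRNA against BAZ2A, also called TIP5 (siTIP5), and, in a second experiment, untransfected cells (PC3) and spheres grown in low adhesion dishes in serum-free medium with growth factors. Peak lists were used for 2 ChIP-seq samples, H3K14 acetylation (H3K14ac) and HA-tagged TIP5 (HA-TIP5). The other 7 ChIP-seq samples, among them the bromodomain mutant of TIP5, the other histone marks and the inputs, were not analysed here. Per the labels' protocols, the RNA was enriched for poly(A) before library preparation. The labels give no batch and do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

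The siRNA experiment's table gives RPKM per gene, as deposited by the authors (reads per kilobase of gene, scaled to the library's reads). Per the submitters' processing notes, Subread 1.4.6-p4, edgeR 3.12.0 and the build hg38/GRCh38 were among the tools and builds used, and no role is given for each. For part of the genes the low RPKM values show whole reads divided by the genomic span of the gene, introns included: for 511 genes with 1 implied read in siCTL replicate 1, 100% of 583 values in the other 3 libraries were within 0.05 of a whole read. Over all low values the share was 53.6 to 54.8% per library, with gene spans taken from a gene table that need not be the authors' annotation. The implied totals were 54.2 and 63.3 M reads for siCTL and 46.4 and 45.9 M for siTIP5. Where introns count as length, RPKM is low for long genes and a minimum RPKM favours short ones.

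The sphere experiment's table holds log2 values, as deposited by the authors on a scale of 0 to 18.5, and the normalization behind these log2 values is not given in the sources used here. Depth is therefore unknown for these 4 libraries. An exact 0 is the lowest value and may be a failed estimate: EEF1G, a translation elongation factor of every cell, is at 0 in PC3 replicate 2. Genes are therefore called listed at 0, and no fold is given against a group at 0. Spheres replicate 2 has 2954 genes between 0 and 2, a range that holds 0 genes in the other 3 libraries.

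The authors also deposited a table per comparison with log2 fold changes and p-values, without a statement on adjustment. The siRNA table lists 3323 genes, 1566 higher and 1757 lower, with a smallest absolute log2 fold change of 0.58. The sphere table lists 1906 genes, 922 higher and 984 lower, with a smallest absolute value of 1. In the peak lists the score per peak is the authors' own value, deposited without a header, and was used only to rank peaks within a list. Per the submitters' processing notes, Bowtie2 2.2.5, SAMtools 1.9, deepTools 2.0.1, MACS2 2.0 and ChIPseeker were used for the ChIP-seq samples. The H3K14ac list holds 37792 single-base summits and the HA-TIP5 list 96350 intervals of 207 to 3582 bp (median 274 bp). Each list comes from 1 sample, so no replicate check exists.

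The count test that had been planned could not be used, since neither table holds counts. The alternative written before the data were examined, limma's trended empirical Bayes fit, was used on log2(RPKM + 0.5) of genes with an RPKM of 1 or more in at least 2 libraries. This left 6279 genes. Fold changes are on the log2(RPKM + 0.5) scale, which understates changes of low genes. For the sphere table the same fit was run on the deposited log2 values after centring each library on its median, for genes with a log2 value of 5 or more in at least 2 libraries (13860 genes). Centring and this minimum were set after the unit was known. Fits used limma 3.58.1 in R 4.3.3, without a replicate block, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Each comparison was fitted within its own table. Of the rows, 93% of the siRNA table and 98.7% of the sphere table matched a symbol of the gene table by name. Of rows that shared a name the one with the highest mean was kept.

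Gene lists (30, fixed before the data were examined) were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, all of limma, for lists with at least 3 tested members. Camera compares a list with the other genes. With an estimated correlation its test also rests on the residual degrees of freedom, which are few with 2 libraries per group. A call lost in that setting therefore does not show that correlation between members is the cause. In spheres the cholesterol list had an estimated correlation of -0.0395, below the preset 0.01, and still a camera adjusted p of 0.189. Other lists had high estimates, such as 0.814 for interferon-stimulated genes with siTIP5. For such lists the preset value may give too small a p-value. Fry's directional p asks whether the members move one way on balance, without a comparison with other genes. The adjusted p of a list is adjusted over the lists of that comparison. Counts of members are given over all genes tested and adjusted over the list alone.

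Genes named in the text were chosen by a rule fixed before the data were examined. They are BAZ2A, then the 10 largest rises and the 10 largest falls among genes past the threshold whose groups did not overlap, then up to 4 members of each list with the smallest p. A mean RPKM of 1 was required, or for spheres, set after the unit was known, a mean of at least 5 in 1 M of the summed linear values, and clone, LOC and antisense names were left out. For peaks the rule takes the 5 HA-TIP5 peaks with the highest score and the peaks nearest to named genes. Other genes are named as chosen after their values were seen. The results of some genes that the rule takes are not reported here. Counting by strand is not stated, so reads of overlapping genes and of close paralogs may have been split between them.

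Peaks on chromosomes 1 to 22 and X were kept (96202 HA-TIP5 peaks and 37786 H3K14ac summits). An overlap was a summit inside an HA-TIP5 peak, and 1000 random placements of the HA-TIP5 peaks on the same chromosome gave the chance value, without a mask of unassembled sequence. Gene spans came from a RefSeq gene table of GRCh38.p14, the build named in the labels' notes. That table gives no strand, so a peak centre within 1 kb of either end of a gene replaced the promoter, and a distal peak was assigned to the gene with the nearest end within 50 kb. A distal peak was any peak with its centre over 1 kb from the nearest gene end, inside a gene or between genes. The same gene could have distal peaks with a summit and distal peaks without one. Genes that changed were compared with all other tested genes by Fisher's exact test (two-sided, 20 tests, Benjamini-Hochberg adjusted), with a Cochran-Mantel-Haenszel odds ratio over 10 bins of mean expression beside it. The overlap of changed genes between the comparisons used Fisher's exact test (two-sided, 4 tests).

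The fits were tested on simulated data with 200 changed genes each. In the siRNA design, with 6279 genes, 90.6% of genes changed by 0.5 on the log2 scale were recovered, and 98.5% of those changed by 1. In the sphere design, with 13860 genes, the shares were 11.5% and 66.2%. False calls were 4.9% and 4.1% of calls. In the data far more genes passed the threshold, 55.2% with siTIP5 and 36.9% in spheres, and the simulated noise was independent between genes. These shares therefore need not hold for the data. Other pseudocounts, filters, scalings, a replicate block, voom weights on recovered reads, stricter peak lists and distances, and the loss of each library in turn were run as alternatives. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 was used for the peaks and overlaps, and matplotlib for the figures.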

Results

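RNA levels were measured in PC3 cells, a human prostate cancer cell line, in 2 experiments. The first compared 2 libraries of cells transfected with an siRNA against BAZ2A (siTIP5) with 2 libraries of cells given a control siRNA (siCTL). BAZ2A, also called TIP5, is the large subunit of the chromatin remodelling complex NoRC and carries a bromodomain that binds acetylated histone H3. The second experiment compared 2 libraries of spheres, a culture form enriched for cells with stem-like properties, with 2 libraries of PC3 cells grown in the usual serum-containing medium. ChIP-seq peak lists from PC3 cells gave the positions of HA-tagged TIP5 and of H3K14 acetylation. By its title the study asked how BAZ2A acts at H3K14ac-marked enhancers in prostate cancer stem cells. The siRNA libraries held 45.9 to 63.3 M implied reads, and the depth of the sphere libraries is unknown.

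BAZ2A itself fell in both siTIP5 libraries. Its RPKM was 2.80 ± 0.14 (SD, n = 2) in siCTL and 0.46 ± 0.0183 (SD, n = 2) in siTIP5, a ratio of 0.164, with a log2 fold change of -1.78 (SE 0.07, limma adjusted p = 1.71e-05). BAZ2A lies on chromosome 12 at 56595596 to 56638318 (GRCh38). Among the 5 other measured subunits of NoRC and the related ISWI remodellers, BAZ1B (not past the threshold without siCTL replicate 1) and CHRAC1 rose and POLE3, SMARCA1 and SMARCA5 fell. POLE3, which also belongs to DNA polymerase epsilon, fell by 0.86 (SE 0.07) and the ATPase SMARCA5 by 0.39. With BAZ2A, 2 members of this list rose and 4 fell, also when adjusted over the list alone, and the list did not stand apart from other genes (camera adjusted p = 0.262, but 0.0291 without siCTL replicate 2).

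With BAZ2A depleted, 23 of 25 amino acid response genes and 15 of 23 cholesterol synthesis genes rose, and 19 of 20 interferon-stimulated genes and 18 of 22 genes of G2 and mitosis fell. GDF15, a secreted stress cytokine of the TGF-beta family, went from an RPKM of 2.34 ± 0.0384 to 43.6 ± 8.30 (SD, n = 2 each), a log2 fold change of 3.94 (SE 0.12, limma adjusted p = 1.21e-05). INHBB, a subunit of activin and inhibin, rose from 3.30 ± 0.102 to 31.4 ± 2.21, and CPA4, a carboxypeptidase, from 0.143 ± 0.00261 to 4.50 ± 0.0733. KRT81, a hair keratin, rose from 80.9 ± 4.39 to 516 ± 61. The cytokine IL24 rose by a log2 fold change of 2.22 (SE 0.06), the stress transcription factor DDIT3 by 2.06 (SE 0.06) and the homeobox gene HOXB9 by 2.05 (SE 0.08). LINC01293, KRT87P and MIR3189 complete the 10 largest rises, at 2.18, 2.11 and 3.11. MIR3189 lies inside GDF15, and KRT87P is a pseudogene near KRT81 on the same chromosome and close to it in sequence, so neither is certain to have risen on its own.

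The largest fall was in TCN1, a vitamin B12 binding protein, from an RPKM of 5.51 ± 0.206 to 0.187 ± 0.0192 (SD, n = 2 each; log2 fold change -3.13, SE 0.07, limma adjusted p = 4.31e-06). HEY1, a Notch target and transcriptional repressor, fell from 25.0 ± 0.586 to 2.87 ± 0.00131. PHB2, a mitochondrial prohibitin, fell from 45.5 ± 0.899 to 8.20 ± 0.353, and the cell adhesion gene AMIGO2 from 12.8 ± 0.503 to 2.64 ± 0.161. The interferon signalling factor IRF9 fell from 10.7 ± 2.92 to 1.89 ± 0.0501, and the interferon-induced IFI6 and GBP3 fell by 2.02 (SE 0.37) and 2.00 (SE 0.08) on the log2 scale. The size of the fall in IFI6 depends on the siCTL library, with an RPKM of 4.94 and 13.1 in siCTL against 1.74 and 1.50 in siTIP5. NXT2, ASB9 and the long noncoding RNA MANCR fell by 2.00, 2.00 and 1.95. In total 1632 genes were higher and 1832 lower of 6279 tested (55.2%), with a median absolute log2 fold change of 0.43 among them. Of these, 111 were higher and 145 lower by at least 1 on the log2 scale.

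**Figure D1:**
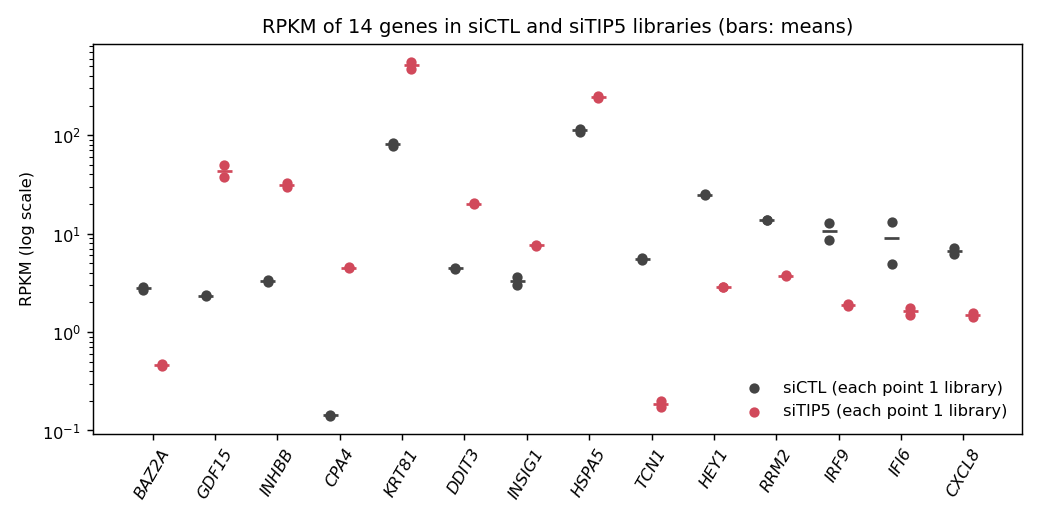
RPKM on a log scale for 14 genes in the 2 siCTL libraries (grey) and the 2 siTIP5 libraries (red), with each point 1 library and each bar the mean of 2. BAZ2A lies at 2.70 and 2.90 in siCTL and at 0.447 and 0.473 in siTIP5, and the 2 siCTL libraries stand apart for IFI6, at 4.94 and 13.1.

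The amino acid response, genes induced by the transcription factor ATF4, rose as a group with siTIP5. Of 25 measured members 23 rose, 0 fell and 2 did not pass the test, also when adjusted over the list alone, with a median log2 fold change of 1.03 (camera adjusted p = 4.28e-11). The call was lost with an estimated correlation (adjusted p = 0.562 with an estimated correlation). Besides DDIT3, the secreted glycoprotein STC2 rose by 1.74 (SE 0.07), the stress sensor SESN2 by 1.97 (SE 0.08) and asparagine synthetase ASNS by 1.65 (SE 0.07). In the unfolded protein response, 14 of 18 members rose and 2 fell (camera adjusted p = 0.000304; adjusted p = 0.562 with an estimated correlation), with the same counts adjusted over the list alone. The chaperone HSPA5 went from an RPKM of 112 ± 6.04 to 243 ± 7.11 (SD, n = 2 each), and HERPUD1 and CANX rose by 1.18 (SE 0.07) and 1.05 (SE 0.08). The chaperone CALR fell by 0.85 and the translocon subunit SEC61B by 0.41.

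Lipid synthesis genes rose too. In cholesterol synthesis 15 of 23 members rose and 0 fell, or 16 adjusted over the list alone (camera adjusted p = 3.63e-05; adjusted p = 0.562 with an estimated correlation). The sterol sensor INSIG1 rose by 1.09 (SE 0.09) and SREBF2, a transcription factor that drives the pathway, by 0.84 (SE 0.07). Of 9 fatty acid synthesis genes 6 rose and 0 fell, also adjusted over the list alone, among them FASN at 1.09 (SE 0.10) and the desaturase SCD at 0.59 (SE 0.07). Their camera adjusted p was 0.00617, 0.0554 without siCTL replicate 2, and 0.562 with an estimated correlation. All 6 measured polyadenylated histone transcripts rose, also adjusted over the list alone, among them H2BC12 from an RPKM of 36.1 ± 1.64 to 74.3 ± 8.25 (SD, n = 2 each; list camera adjusted p = 0.00183; adjusted p = 0.562 with an estimated correlation). In the same libraries the nuclear retained RNA NEAT1 was higher by 0.58 (SE 0.08), and 4 of 13 mitochondrially encoded transcripts fell, such as MT-CO3 by 0.55 (SE 0.09).

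Interferon-stimulated genes fell as a group: 19 of 20 members fell and 0 rose, also adjusted over the list alone, with a median log2 fold change of -0.93 (camera adjusted p = 1.28e-05). That call was lost with an estimated correlation (adjusted p = 0.729 with an estimated correlation), and fry's directional adjusted p was 0.0619. The antiviral gene SAMD9 fell by 1.82 (SE 0.08), BST2 by 1.26 (SE 0.12) and PARP9 by 0.87 (SE 0.10). The siCTL libraries differed in these genes, as IRF9 shows with an RPKM of 8.62 and 12.8 against 1.85 and 1.93 in siTIP5. Of 22 genes of G2 and mitosis 18 fell and 1 rose, or 19 and 1 adjusted over the list alone (camera adjusted p = 0.00103; 0.0815 without siCTL replicate 2; adjusted p = 0.729 with an estimated correlation). Examples are the spindle factor TPX2, with a log2 fold change of -0.59 (SE 0.07), and topoisomerase TOP2A at -0.61 (SE 0.08), while the survivin gene BIRC5 rose by 0.24. Of 22 S phase genes 9 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.183, but fry's directional adjusted p = 0.00788). RRM2, the small subunit of ribonucleotide reductase, fell from an RPKM of 13.6 ± 0.022 to 3.73 ± 0.0625.

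Other lists moved in both directions with siTIP5 or did not stand apart from other genes. Of 13 prostate stem and progenitor markers 5 rose and 5 fell, with the aldehyde dehydrogenase ALDH1A3 at 0.78 (SE 0.07) and ITGB1 at 0.72 (SE 0.07), and SOX9 at -0.83 (SE 0.06) and ITGA6 at -0.89 (SE 0.08). The list's camera adjusted p was 0.745, and adjusted over the list alone the counts were the same. Counts of rises and falls were 9 and 4 of 20 for cytoskeleton and SRF/YAP targets (adjusted p = 0.196), 7 and 8 of 21 for extracellular matrix and integrins (0.781), 5 and 5 of 14 for mesenchymal markers (0.747) and 3 and 3 of 12 for epithelial markers (0.745). Matrix genes that fell include COL6A2 at -0.98 (SE 0.08) and fibronectin FN1 at -0.78 (SE 0.07), while the laminin LAMB3 rose by 1.36 (SE 0.08). In hypoxia and glycolysis 9 of 22 rose and 3 fell (0.135), with the angiogenic factor VEGFA at 1.59. Immediate early genes had 10 rises and 5 falls of 21 (0.259), with the phosphatase DUSP5 at 1.43 (SE 0.07), and NRF2 targets 6 and 2 of 16 (0.392), with heme oxygenase HMOX1 at 0.94 (SE 0.11).

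In the NF-kB and cytokine list 3 of 11 rose and 5 fell (camera adjusted p = 0.745): the chemokine CXCL8 was at -1.86 (SE 0.09) and the cytokine LIF at 1.39 (SE 0.08). Notch, Wnt and Hedgehog targets had 3 rises and 3 falls of 7 (0.994), with HES1 at -0.74 and HES4 at 1.24. Of 22 rRNA synthesis and nucleolar genes 7 fell and 0 rose (0.392, but fry's directional adjusted p = 0.00788), with NPM1 at -0.40 (SE 0.08). In the remaining lists 1 rose and 1 fell of 5 PRC2 and H3K14 acetyltransferase genes (0.745), of 4 basal markers (0.983), of 3 neuroendocrine markers (0.745) and of 4 squamous genes (0.994), and 2 rose and 1 fell of 3 androgen response genes (0.582). NDRG1 rose by 1.70 (SE 0.07) and HOXB13, a prostate homeobox factor, fell by 0.95 (SE 0.07). Adjusted over the list alone these counts moved by at most 1 gene. The RNA quality lists had adjusted p of 0.245 for mitochondrial transcripts, with 4 falls of 13, and 0.202 for nuclear retained RNA, with 1 rise of 7, or 3 with median-of-ratios scaling. Of markers of other cell types 0 leukocyte genes reached the RPKM minimum, the fibroblast list had COL1A1, which fell by 0.37 (SE 0.06), and the endothelial and neural list had TUBB3 at 0.00 (SE 0.09). With a filter of 1 RPM (recovered reads scaled to the library total) in place of an RPKM of 1, which keeps long genes, 2855 genes were higher and 3632 lower of 12330.

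In spheres 25 of 26 cholesterol synthesis genes rose relative to PC3 cells, and 16 of 22 mesenchymal markers and 24 of 36 extracellular matrix and integrin genes fell. Here and below, sphere growth, the lack of serum and the added growth factors go together, so their effects cannot be told apart. BAZ2A did not pass the test, with log2 values of 11.2 ± 0.05 in PC3 and 11.35 ± 0.17 in spheres (SD, n = 2 each; centred log2 fold change -0.06, SE 0.11, limma adjusted p = 0.72), and the sign of that difference depends on the centring. COL1A2, a chain of type I collagen, had log2 values of 3.92 ± 0.24 in PC3 and 11.38 ± 0.02 in spheres (log2 fold change 7.26, SE 0.18, limma adjusted p = 4.29e-12). The matrix protein SPARC rose by 5.93 (SE 0.15), the mucus protein FCGBP by 4.68 (SE 0.17), the mucin MUC13 by 4.58 (SE 0.29) and PKMP5, a pseudogene of pyruvate kinase that may share its reads, by 4.97 (SE 0.31). PPP1R1B, a regulator of protein phosphatase 1, was listed at 0 in both PC3 libraries and at 9.66 and 9.65 in spheres, and the keratin KRT20 at 0 and at 7.76 and 7.73. SPINK5, a protease inhibitor, had 3.84 and 0 in PC3 and 7.40 and 7.42 in spheres. EEF1G stood at 9.45 and 0 in PC3 and at 10.4 and 11.4 in spheres.

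The largest falls in spheres were in hair keratins. KRT81 had log2 values of 13.61 ± 0.31 in PC3 and 7.54 ± 0.47 in spheres (SD, n = 2 each; log2 fold change -6.28, SE 0.19, limma adjusted p = 2.67e-11), and KRT86 fell by 6.26 (SE 0.18). The 2 genes overlap and are close paralogs, so their reads may not be told apart. ID3, an inhibitor of helix-loop-helix factors induced by BMP signals, fell by 5.06 (SE 0.27), the chemokine CXCL8 by 5.01 (SE 0.22), the collagen COL6A3 by 4.64 (SE 0.18), the proteoglycan SRGN by 4.64 (SE 0.20) and the chloride channel ANO1 by 4.49 (SE 0.20). LRRC38, the serpin SERPINB7 and the homeobox gene GBX2 fell by 5.38, 4.60 and 4.50. In total 2713 genes were higher and 2399 lower of 13860 after centring, 675 and 596 of them by at least 1 on the log2 scale. As deposited, the median tested gene was 0.24 higher in spheres on the log2 scale, and without centring 4978 genes were higher and 1325 lower, so that 79% of calls were higher in place of 53.1%. Without spheres replicate 2, the library with many values between 0 and 2, 1637 were higher and 1494 lower.

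Cholesterol synthesis genes rose together in spheres: 25 of 26 members rose and 0 fell, also adjusted over the list alone and under each scaling tried, with a median log2 fold change of 1.96 (camera adjusted p = 1.15e-26; adjusted p = 0.189 with an estimated correlation). HMGCS1, the first committed synthase of the pathway, rose by 3.21 (SE 0.12), the epoxidase SQLE by 2.79 (SE 0.11) and the oxidase MSMO1 by 3.31 (SE 0.14). Of 16 fatty acid synthesis genes 12 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 4.72e-07; adjusted p = 0.275 with an estimated correlation), with SCD at 1.74 (SE 0.10) and the acetyl-CoA synthetase ACSS2 at 2.00 (SE 0.10). In the amino acid response 17 of 29 rose and 0 fell, or 17 and 2 adjusted over the list alone (camera adjusted p = 0.000136; adjusted p = 0.286 with an estimated correlation), with NUPR1 at 1.16 (SE 0.13) and ATF4 at 0.72 (SE 0.10). In the unfolded protein response 10 of 22 rose and 1 fell, or 12 and 1 adjusted over the list alone and 17 and 1 without centring (camera adjusted p = 0.00202; adjusted p = 0.392 with an estimated correlation), with HERPUD1 at 1.11 (SE 0.11) and XBP1 at 0.95 (SE 0.12).

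Mesenchymal and matrix genes mostly fell in spheres. Of 22 mesenchymal markers 16 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 1.18e-09; adjusted p = 0.275 with an estimated correlation). The receptor kinase AXL fell by 3.37 (SE 0.12), the matrix protein TNC by 2.05 (SE 0.10) and the protease MMP14 by 2.08 (SE 0.11), whereas SPARC and LOX rose, at 5.93 and 2.36. Of 36 extracellular matrix and integrin genes 24 fell and 5 rose, also adjusted over the list alone (camera adjusted p = 9.81e-08; adjusted p = 0.286 with an estimated correlation), with COL12A1 at -3.57 (SE 0.14) and LAMB3 at -2.25 (SE 0.13). Cytoskeleton and SRF/YAP targets had 12 falls and 1 rise of 22, also adjusted over the list alone (camera adjusted p = 2.26e-05; adjusted p = 0.401 with an estimated correlation), or 11 falls and 5 rises without centring. Of 23 epithelial markers 10 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.033; adjusted p = 0.428 with an estimated correlation; 0.087 without PC3 replicate 1). E-cadherin CDH1 rose by 2.30 (SE 0.18), EPCAM by 1.74 (SE 0.14) and the splicing factor ESRP1 by 3.58 (SE 0.23), while the keratin KRT7 fell by 3.19. Basal markers had 6 falls and 1 rise of 8, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.000133; adjusted p = 0.286 with an estimated correlation), with the growth factor receptor EGFR at -1.66 (SE 0.11) and KRT15 at 1.25 (SE 0.15).

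Proliferation genes were lower in spheres relative to the median gene. Of 31 genes of G2 and mitosis 19 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 9.31e-07; adjusted p = 0.428 with an estimated correlation), but 5 fell without centring. MKI67, the Ki-67 antigen, fell by 0.70 (SE 0.11) and the mitotic kinase PLK1 by 0.77 (SE 0.12). Of 31 S phase genes 15 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 1.07e-05; adjusted p = 0.392 with an estimated correlation), against 9 falls and 1 rise without centring, with thymidine kinase TK1 at -1.04 (SE 0.12). In hypoxia and glycolysis 18 of 30 fell and 2 rose, or 19 and 2 adjusted over the list alone, but 12 and 4 without centring, where the median moved from -0.37 to -0.16 (camera adjusted p = 0.000118; adjusted p = 0.286 with an estimated correlation), with carbonic anhydrase CA9 at -1.74 (SE 0.27). Of 10 polyadenylated histone transcripts 5 rose and 0 fell, or 6 and 0 adjusted over the list alone and 8 and 0 without centring (camera adjusted p = 0.0043; adjusted p = 0.474 with an estimated correlation), with H2AC6 at 1.78 (SE 0.15). All 13 mitochondrially encoded transcripts were higher in spheres, or 12 with median-of-ratios scaling and 9 with quantile normalization, with MT-CO3 at 0.81 (SE 0.11) and a median of 0.67 (camera adjusted p = 6.8e-07; adjusted p = 0.401 with an estimated correlation). Of 9 nuclear retained RNAs 3 rose and 0 fell, or 5 and 0 without centring (camera adjusted p = 0.0457; adjusted p = 0.479 with an estimated correlation; 0.139 without spheres replicate 1 and 0.0833 without PC3 replicate 2), with NEAT1 at 1.42 (SE 0.11).

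Markers of other cell types were few in the sphere libraries, with an exception among fibroblast markers. Of 6 measured fibroblast genes 4 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.000938; adjusted p = 0.286 with an estimated correlation). COL1A2 and COL3A1 rose by 7.26 (SE 0.18) and 3.40 (SE 0.28), PDGFRA rose by 1.57 (SE 0.17), and LUM was listed at 0 and 0 in PC3 and at 6.49 and 7.16 in spheres. COL1A1 did not pass the test at 0.25 (SE 0.19), FBLN1 fell by 0.84, and DCN was listed at 0 in 3 libraries and at 0.35 in spheres replicate 2. Of the endothelial and neural list 2 of 5 rose and 1 fell, or 3 and 0 without centring (camera adjusted p = 0.227), with the VEGF receptor KDR at 2.01 (SE 0.13). The leukocyte list had 1 measured gene, CD68, a lysosomal protein of macrophages, with log2 values of 5.16 and 5.71 in PC3 and of 5.34 in spheres replicate 1. Its fitted fall of 2.27 (SE 0.84, limma adjusted p = 0.0485) came from spheres replicate 2, without which its adjusted p was 0.624 (0.116 without PC3 replicate 2), and did not pass without centring, with median-of-ratios scaling or with the other filters.

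The other lists did not stand apart from the rest of the genes in spheres. Of 17 prostate stem and progenitor markers 4 rose and 7 fell (camera adjusted p = 0.212, but fry's directional adjusted p = 0.0113). Without centring 6 rose and 6 fell, and their median turned from -0.12 to 0.09. The Wnt receptor LGR5 was at 1.78 (SE 0.19) and MYC at 1.06 (SE 0.10), and ALDH1A3 at -2.32 (SE 0.10) and ITGB4 at -1.37 (SE 0.13). Interferon-stimulated genes had 15 rises and 2 falls of 37 (0.064, but 0.0205 without PC3 replicate 1 and 0.0177 without spheres replicate 2), with the RNA sensor IFIH1 at 1.58 (SE 0.20). Notch, Wnt and Hedgehog targets had 4 rises and 9 falls of 20, or 6 and 6 without centring (0.0575, but 0.0192 without spheres replicate 1), with the Wnt inhibitor DKK1 at -1.32 (SE 0.10). NF-kB and cytokine genes had 7 rises and 7 falls of 18 (0.496), with IL1B at -3.61 (SE 0.16) and ICAM1 at 1.26 (SE 0.12). Counts of rises and falls were 5 and 8 of 22 for immediate early genes, whose median was -0.16 but 0.05 without centring (0.183), 7 and 3 of 21 for NRF2 targets, but 10 and 0 without centring (0.183), 6 and 2 of 12 for androgen response genes (0.272) and 3 and 1 of 7 for squamous genes (0.31, median 0.04 but -0.03 with quantile normalization), of which S100A9 was listed at 0 in PC3 and at 6.35 and 6.24 in spheres. They were 1 and 5 of 16 for PRC2 and H3K14 acetyltransferases, but 5 and 2 without centring (0.38), with KAT2B at 1.12 (SE 0.14), 1 and 2 of 10 for NoRC and ISWI subunits, but 1 and 0 without centring (0.43), 0 and 1 of 5 for neuroendocrine markers (0.716) and 4 and 4 of 26 for rRNA synthesis genes, but 12 and 0 without centring (0.742). Adjusted over the list alone, 0 NoRC and ISWI subunits passed, and Notch, Wnt and Hedgehog targets had 5 rises and 11 falls.

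**Figure D2:**
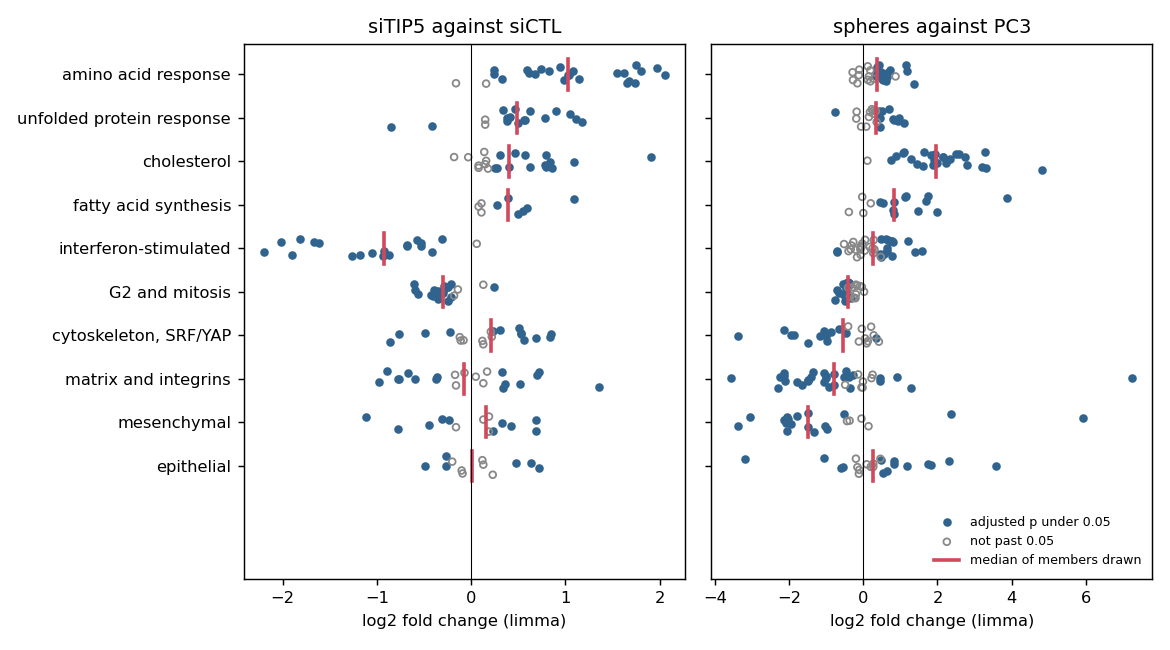
Log2 fold changes of the measured members of 10 gene lists in siTIP5 against siCTL (left) and spheres against PC3 (right), each point 1 gene, filled where the adjusted p was under 0.05, with the median in red and genes listed at 0 in a whole group left out. Cholesterol genes lie to the right of 0 in spheres with 25 of 26 rising, and interferon-stimulated genes to the left with siTIP5 with 19 of 20 falling.

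Genes changed by BAZ2A depletion were compared with genes that differ in spheres, to ask whether they are the same. Genes that rose with siTIP5 fell in spheres more often than independent lists would give: 363 genes against 295.2 (odds ratio 1.44, Fisher's exact test adjusted p = 2.2e-06, 5968 genes tested in both). The hair keratin KRT81, at 2.66 and -6.28 on the log2 scale, CPA4, at 2.96 and -4.18, and the actin crosslinker FLNC, at 1.88 and -3.97, are examples. Genes that fell with siTIP5 rose in spheres in 391 cases against 338.7 (odds ratio 1.30, adjusted p = 0.000414), such as TCN1, at -3.13 and 4.43. Falls in both were fewer than independent lists give, 295 against 332.8 (odds ratio 0.82, adjusted p = 0.00874), and rises in both were 319 against 300.4 (1.11, adjusted p = 0.167). Among genes changed by at least 1 on the log2 scale in both, rises in both (odds ratio 10.56) and falls in both (4.66) were over-represented. Of those 49 genes 19 had opposite signs, among them KRT81, CPA4 and TCN1. The odds ratios of the opposite pairs at that size are not given here, so no switch towards agreement is shown. GDF15, at 3.94 and 2.96, and INSIG1, at 1.09 and 3.29, rose in both. CXCL8, at -1.86 and -5.01, and ID3, at -1.57 and -5.06, fell in both. The calls for falls in both and for falls with siTIP5 and rises in spheres were lost without siTIP5 replicate 2 (0.96 and 1.11), and those for falls in both also without siCTL replicate 1 (1.04), siCTL replicate 2 (0.88), PC3 replicate 2 (0.99) or spheres replicate 2 (0.99). Rises in both passed without siCTL replicate 1 (1.32), siTIP5 replicate 2 (1.22), PC3 replicate 2 (adjusted p = 0.000625) or spheres replicate 2 (1.37). By median length, genes that rose with siTIP5 and genes that fell in spheres were both longer than the other tested genes with a position. Genes that fell with siTIP5 and genes that rose in spheres were both shorter. The overlaps were not tested within bins of gene length, so a shared dependence on length stays open for the opposite pairs. FLNC was chosen after its values were seen.

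Lists differed in how many of their members moved the same way in both comparisons, and these differences were not tested. Of the members measured in both comparisons, 15 of 23 cholesterol genes, 14 of 25 amino acid response genes and 8 of 18 unfolded protein response genes rose in both, with 0 opposite in each. Of 22 genes of G2 and mitosis 11 fell in both and 1 was opposite, and of 22 S phase genes 6 fell in both and 0 were opposite. Of 20 cytoskeleton and SRF/YAP targets 8 rose with siTIP5 and fell in spheres, and 1 did the reverse. Of 21 extracellular matrix and integrin genes 1 rose in both, 6 fell in both and 6 were opposite. Of 20 interferon-stimulated genes 5 fell with siTIP5 and rose in spheres, and 1 fell in both. Across the 5968 genes, which are not independent replicates, the log2 fold changes had a Pearson r of -0.02 and a Spearman rho of -0.06. The comparisons share no library.

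**Figure D3:**
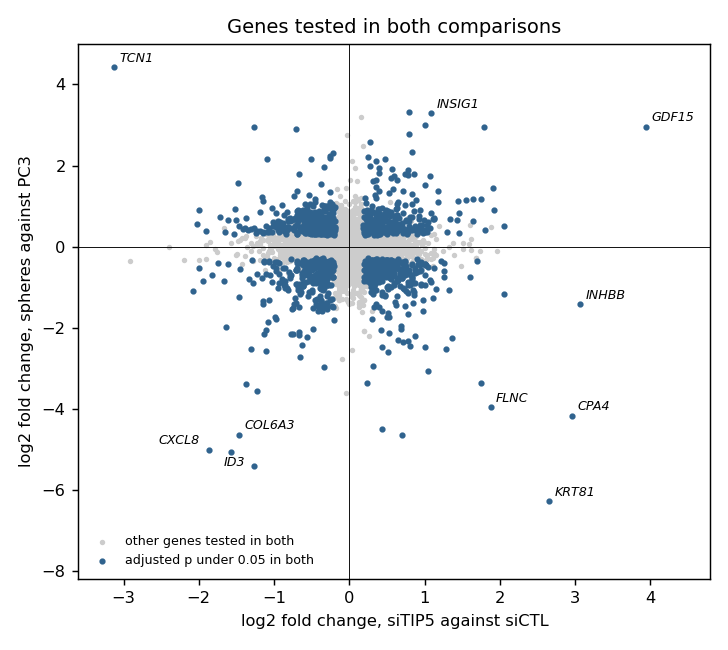
Log2 fold change with siTIP5 (x axis) against log2 fold change in spheres (y axis), each point 1 gene tested in both, blue where the adjusted p was under 0.05 in both, and genes listed at 0 in a whole group of the sphere table left out. KRT81 lies at 2.66 and -6.28, TCN1 at -3.13 and 4.43, and GDF15 at 3.94 and 2.96.

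HA-TIP5 peaks in PC3 cells lay mostly away from gene ends and met H3K14ac summits more often than random placement gives. Of 96202 peaks, 8.2% lay within 1 kb of a gene end, 58.6% inside genes and 33.2% between genes, against 4.9%, 51.5% and 43.6% of random placements. H3K14ac summits lay at gene ends in 27.6% of cases. A summit fell inside 3990 HA-TIP5 peaks (4.15%), against a mean of 441.8 and a highest value of 514 in 1000 random placements, 9.03 times the mean. When peaks were shifted by 10 to 100 kb instead, the mean was 968.1 and the ratio 4.12. Within 1 kb of a summit were 9500 peaks (9.88%), 3.27 times the random mean of 2907.4 but 1.62 times the mean of 5878.2 with shifted peaks. Seen from the other mark, 4004 summits (10.6%) lay inside an HA-TIP5 peak. Chromosomes differed: HA-TIP5 peaks ranged from 8.5 per Mb on chromosome 13 to 87.9 per Mb on chromosome 20. The share of peaks within 1 kb of a summit ranged from 2.4% on chromosome 19 to 17.5% on chromosome 10. The sources of this unevenness were not tested.

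The share of overlapping peaks was lower at higher scores. With the peaks of score above the median in each list, 706 of 48121 HA-TIP5 peaks held a summit, 6.51 times the random mean of 108.5, and 1459 had one within 1 kb, 2.01 times the random mean of 727. The share of HA-TIP5 peaks within 1 kb of a summit was 14.01% in the 10% of peaks with the lowest score and 6.86% in the 10% with the highest, and the share of summits within 1 kb of an HA-TIP5 peak was 30.54% and 2.78%. Among the 10% of highest score in each list 2 of 9701 HA-TIP5 peaks held a summit, against 4.3 in random placements, and 2 had one within 1 kb, against 29, and the causes of this trend were not tested. The 5 HA-TIP5 peaks with the highest score lay on chromosome 10 at 37340089 to 37340410, inside LINC00993, on chromosome 18 at 78113532 to 78113845, on chromosome 3 at 194917665 to 194918073, on chromosome 14 at 28273002 to 28273367 and on chromosome 10 at 36205116 to 36205469 (GRCh38). The last 4 lay outside genes, and none of the 5 had a summit within 1 kb.

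**Figure D4:**
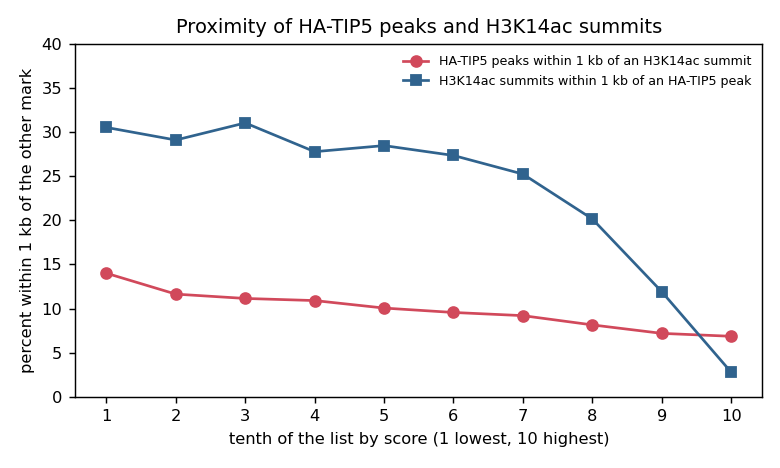
Percent of HA-TIP5 peaks within 1 kb of an H3K14ac summit (red) and of H3K14ac summits within 1 kb of an HA-TIP5 peak (blue), in 10 bins of each list ranked on its own score, lowest at 1. The red line goes from 14.01% to 6.86% and the blue line from 30.54% to 2.78%.

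Genes near HA-TIP5 peaks were over-represented among those that rose with BAZ2A depletion. Of 1546 rising genes with a position, 68.6% were nearest to a distal peak, against 56.9% of the other tested genes (odds ratio 1.66, Fisher's exact test adjusted p = 3.55e-15, and 1.65 within bins of mean expression). A peak at a gene end was found for 21.3% against 15.4% (odds ratio 1.49, adjusted p = 3.89e-07). Among genes that fell both were under-represented, with odds ratios of 0.73 (adjusted p = 1.25e-07, but a lost call within bins of gene length, at 0.89 with a 95% interval of 0.79 to 1.00) for distal peaks and 0.72 (6.62e-05; 0.11 without siTIP5 replicate 2 and 0.324 with the stronger HA-TIP5 peaks) for gene ends. Peaks shifted by 10 to 100 kb gave as low an odds ratio for falls in 34 of 100 draws for distal peaks and 6 of 100 for gene ends. Distal peaks with an H3K14ac summit within 1 kb gave 1.44 (adjusted p = 0.00303, but 0.244 with the 1 RPM filter and 0.322 with the stronger HA-TIP5 peaks) for rising genes. Those without one gave 1.67 (1.25e-15), and the difference between the 2 was not tested. Neither set was run within bins of gene length or with shifted peaks. The 2 sets share genes, since 349 tested genes had the first kind, 3458 the second and 3518 any distal peak. Gene-end peaks with a summit were found for 33 rising genes (1.76, adjusted p = 0.018, but 0.0666 without siCTL replicate 1, 0.175 without siTIP5 replicate 2, 0.26 with the 1 RPM filter and 0.615 with the stronger peaks). Of the largest rises with a position 5 of 9 (KRT81, KRT87P, IL24, CPA4 and INHBB) had a peak inside their span, but not GDF15, and of the largest falls 2 of 10 (IRF9 and ASB9) had. The share over all tested genes was not counted, so these counts show no excess. That of KRT81, on chromosome 12 at 52291384 to 52291699, lay at its gene end. With shifted peaks the odds ratio for rising genes and distal peaks was still 1.46 at the median, and with the stronger HA-TIP5 peaks alone the gene-end association was lost (1.27, adjusted p = 0.0724).

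In spheres the association was with genes that fell. Of 2236 falling genes 70.4% were nearest to a distal peak, against 62.2% of others (odds ratio 1.45, Fisher's exact test adjusted p = 8.21e-13), and 19.9% against 15.1% had a peak at a gene end (adjusted p = 1.25e-07, odds ratio 1.41 within bins of mean expression). For distal peaks with H3K14ac the odds ratio was 1.68 (13.2% against 8.3%, adjusted p = 1.73e-11). Distal peaks without H3K14ac gave 1.45, and the difference was not tested. Neither set was run within bins of gene length or with shifted peaks. Genes that rose in spheres were under-represented, at 0.83 for distal peaks (adjusted p = 0.00013; 0.631 without spheres replicate 2) and 0.72 at gene ends (1.11e-06; 0.116 without PC3 replicate 2). For H3K14ac peaks at gene ends the odds ratios were 1.21 for falls (adjusted p = 0.312, but 0.0117 without PC3 replicate 1) and 0.79 for rises (0.31, but 0.0222 without PC3 replicate 1). Distal peaks with H3K14ac gave 0.94 for rises (adjusted p = 0.47), but 0.80 without centring (0.00139), 0.82 without PC3 replicate 1 (0.0169) and 1.23 without spheres replicate 2 (0.0449). Of the 10 largest rises 6 had an HA-TIP5 peak inside their span, such as COL1A2 with 3, and of the 10 largest falls 5 had, such as ANO1 with 38. Here too the share over all tested genes was not counted, and span length was not taken into account. The gene-end association was lost without PC3 replicate 2 (1.02) and with the stronger HA-TIP5 peaks alone (0.99, adjusted p = 0.963), and shifted peaks gave a median odds ratio of 1.39 for falling genes and distal peaks. Shifted peaks gave a value as far from 1 in 21 of 100 draws for falls and 17 of 100 for rises with distal peaks, and in 3 of 100 and 0 of 100 at gene ends.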

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

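Alternatives chosen after the values were seen are voom with a 1 RPM filter, quantile normalization, the crossed pairing, uncentred values in the overlaps, the 1 RPM filter and gene length bins for peaks. Named genes kept direction and side of the threshold in 2947 values, weakened in 81, strengthened in 27 and reversed in 12, and list medians, under the replicate block, an estimated correlation and the loss of each library alone, did so in 299, 28, 4 and 5, with the scalings not counted. Causes were not tested unless stated. A lone library left in a group was assumed to vary like the other group. Depth is unknown for spheres, where a change of 0.5 was recovered in 11.5% of simulated genes. The edgeR and DESeq2 alternatives were not run, since the tables hold no counts and reads recovered from RPKM and gene spans, used with voom alone, are estimates, nor overlaps by covered share, as summits are single bases.

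Genes higher and lower with siTIP5 (1632 and 1832) were 2855 and 3632 with a filter of 1 RPM, which tests more genes, 3225 and 4004 with voom on that filter, 111 and 145 at an absolute log2 fold change of 1 or more, and 1076 and 1221 at an adjusted p under 0.01. In spheres (2713 and 2399) they were 4978 and 1325 as deposited, 675 and 596 at an absolute log2 fold change of 1 or more, and 1667 and 1456 at an adjusted p under 0.01. With no filter 1644 were higher. Leaving out each library gave 1637 to 2935 higher and 1494 to 2588 lower. Of the lists, 7 with siTIP5 and 16 in spheres passed, against 0 and 0 with an estimated correlation, and fry passed 15 with siTIP5. Those 15 include lists that camera did not pass, such as S phase and rRNA synthesis, and fry makes no comparison with other genes. The setting with an estimated correlation rests on few degrees of freedom, so the loss of calls there does not by itself show correlation between members. The estimate was 0.814 for interferon-stimulated genes with siTIP5. It was 0.583 for histone transcripts and 0.491 for mitochondrial transcripts in spheres. For these lists correlation may add to the loss.

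With the replicate block, 2077 and 2230 genes were higher and lower with siTIP5, and 2397 and 2189 in spheres. Same-numbered libraries deviated with a correlation of 0.33 and -0.15, and with 2 pairs each the numbers were not taken as pairs. The crossed pairing in spheres gave 3398 and 3016. The block ended the call of H3K14ac peaks at gene ends among rising genes (1.56).

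For genes changed in both comparisons, the odds ratios of rises in both and falls in both were 1.18 and 0.98 with the 1 RPM filter, 10.56 and 4.66 at an absolute log2 fold change of 1 or more, and 0.94 and 0.93 as deposited. Leaving out each library gave 0.94 to 1.37 and 0.71 to 1.04, and 1.11 to 1.51 for falls with siTIP5 and rises in spheres. For peaks, the 10% of highest score in each list overlapped at 0.47 times the random mean, or 0.07 times within 1 kb.

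For genes near peaks with siTIP5, peaks of score above the median gave 1.27 (rises) and 0.86 (falls) at gene ends, 1.4 and 1.22 at gene ends with H3K14ac, and 1.27 for rises and distal H3K14ac peaks. The 1 RPM filter gave 1.23 and 1.04 at gene ends with H3K14ac, and 1.11 and 1.04 for distal H3K14ac peaks. Length bins gave 0.89 for falls and distal peaks. Leaving out each library gave 0.63 to 0.87 for falls at gene ends, and 1.45 to 2.15 (rises) and 1.00 to 1.21 (falls) at gene ends with H3K14ac.

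In spheres, peaks of score above the median gave 0.91 (rises) and 0.99 (falls) at gene ends, 0.83 for falls at gene ends with H3K14ac and 1.01 for rises and distal H3K14ac peaks. The latter was 1.01 at 20 kb and 0.80 as deposited, which passed, and falls at gene ends with H3K14ac within 3 kb gave 1.41. Leaving out each library gave, for rises, 0.62 to 0.89 at gene ends, 0.63 to 1.08 there with H3K14ac, 0.79 to 0.97 for distal peaks, 0.82 to 1.23 for those with H3K14ac and 0.78 to 0.95 for those without, and for falls 1.02 to 1.77 at gene ends and 1.03 to 1.53 there with H3K14ac.

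Values that turned their sign, none past the threshold once turned, were TUBB3 (-0.00 with voom under both filters, -0.10 to 0.10 leaving out each library), KRT15 (-0.01 to 0.15) and PI3 (-0.08 to 0.03) with siTIP5, and in spheres BAZ2A (0.15 as deposited, -0.18 to 0.06), BAZ2B (-0.49 to 0.00), POU3F2 (0.02 as deposited) and FTH1, a call at 0.45 that ended with quantile normalization (-0.03). List medians did so for epithelial markers with siTIP5 (-0.06 to 0.15) and in spheres for neuroendocrine (-0.07 to 0.24), NF-kB (-0.07 to 0.20) and squamous genes (-0.08 to 0.34), and as deposited for PRC2 and H3K14 acetyltransferases (0.13), NoRC and ISWI subunits (0.15), immediate early genes (0.05) and stem markers (0.09).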

Other observations

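The tests of admixed fibroblasts were chosen after the result was seen, as were ID1, ID2 and the other genes listed first here. ID1, ID2 and ID3, inhibitors of helix-loop-helix factors that BMP signals induce, fell in both comparisons, by 1.37, 1.47 and 1.57 on the log2 scale with siTIP5 and by 3.38, 1.24 and 5.06 in spheres (each past the threshold with limma). The hyaluronan synthase HAS2 and the cytokine CSF3 fell too, at -1.22 and -1.26 with siTIP5 and -3.56 and -5.42 in spheres. TFF3, a mucosal trefoil peptide, rose in both, at 1.79 and 2.94, as did INSIG1 at 1.09 and 3.29. The kinase FAM20C went opposite ways, at 1.75 and -3.37, and the transporter SLC7A8 at -1.48 and 1.57.

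Genes near HA-TIP5 peaks were more frequent among rises with siTIP5 and among falls in spheres. Within 10 bins of gene length the odds ratio for distal peaks was 1.39 (95% interval 1.22 to 1.58) for rises with siTIP5. For falls in spheres it was 1.35 (1.22 to 1.50). These values argue against gene length as the whole cause, but lengths still differ within a bin, so length is not excluded. Bins of gene length and shifted peaks were not combined. Distal peaks shifted by 10 to 100 kb gave an odds ratio as large in 0 of 100 draws for siTIP5, though their median was 1.46 against 1.66, and in 21 of 100 draws for spheres. Peak-rich neighbourhoods could therefore account for the distal result in spheres, and for distal peaks with siTIP5 they leave a small part that may reflect the positions themselves; at gene ends shifted peaks reached the odds ratio in 0 of 100 draws for siTIP5 and 3 of 100 for spheres, but both calls were lost with the stronger HA-TIP5 peaks (1.27 and 0.99), and that in spheres without PC3 replicate 2 (1.02). Whether bound TIP5 represses these genes is a hypothesis that these lists do not test.

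Interferon-stimulated genes were lower with siTIP5, and the siCTL libraries differed in them. A raised interferon response in siCTL replicate 2 alone is argued against as the whole cause by the median without that library, -0.75. A response to transfection that both siCTL libraries share, or a difference between siRNAs in this response, could give the same fall and stays open, since 1 siRNA per group cannot separate it from the loss of BAZ2A.

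Fibroblast-list genes were higher in spheres. Admixed fibroblasts would bring their other abundant collagens with COL1A2, at log2 values of 11.39 and 11.37 in spheres. COL1A1, with which COL1A2 forms type I collagen, had a log2 fold change of 0.25 (SE 0.19) and stood at 7.60 and 7.53, and COL3A1 at 7.22 and 7.17, which argues against admixture as the source of COL1A2. For COL3A1 and LUM admixture and expression by the sphere cells cannot be told apart. The low DCN (0 and 0.35) and POSTN (0 and 0.17) in spheres count against admixture, but a 0 may be a failed estimate. The fibroblast marker MGP went the other way, listed at 0 and 0 in PC3 and at 3.57 and 3.88 in spheres. The collagen levels of such fibroblasts are unknown. Expression of COL1A2 by the sphere cells themselves may be the source, as a hypothesis.

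In the authors' deposited table for the siRNA experiment, BAZ2A has a log2 fold change of -2.52. Of the authors' listed genes tested here, 1256 of 1256 had the same sign for siTIP5 and 1076 of 1172 for spheres. In spheres 146 differed by over 3 on the log2 scale, 64 of them pseudogenes against 66 of the other 1026 (Fisher's exact test p = 3.01e-29). CCT8P1, a pseudogene, has -15.63 in the authors' deposited table and log2 values of 10.28 and 10.32 in PC3 and 10.47 and 10.57 in spheres. The highest H3K14ac scores lay on chromosome 12 at 65825494, inside HMGA2, and on chromosome 10 at 33336750, 2083 bp from NRP1.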
